A study of Homo sapiens with 6 samples.

How the data were processed

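Libraries of U87 cells, 3 per siRNA, were compared. Per the labels' protocols, poly(A) RNA was converted to strand-marked libraries with dUTP and read as 2 × 150 bases on a NovaSeq instrument. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2, with the genome build GRCh38. The annotation release, the step that made the counts and its use of strand are not given in the sources used here, so genes that overlap, on either strand, may share counts.

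The deposited table gives an expected count, already a whole number, and an FPKM value for each gene and library, so rounding changed no value. The deposited FPKM values show 1e-04 where a gene has no count. Low counts pile up at multiples of 4: in control library 1, 421, 1377 and 273 genes had 3, 4 and 5 counts and 253, 685 and 189 had 7, 8 and 9. Assuming that a read pair is worth about 4 counts, the totals of 57077251 to 61767069 counts would stand for about 4 times fewer pairs. Counting error is larger than the counts alone imply, and the spread between libraries, which the tests estimate, includes it. The floor of 3 counts was 0.0486 to 0.0526 CPM, and at 4 counts per pair it would be 12 counts. Gene names were taken from the table, and 731 of 738 list entries were matched to it through names and RefSeq synonyms.

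The plan named a limma test on log2(FPKM + 1) for a table of FPKM, and edgeR if counts were present. As counts are present, the main test was edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, TMM scaling, filterByExpr, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 18322 of the 29918 genes with a count in at least 1 library. Standard errors are the unshrunk log2 difference over the square root of the F statistic. CPM values are TMM-scaled. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 28 lists, with an estimated correlation and fry beside it. The setting with an estimated correlation also gave higher p-values where the estimate lay under the preset (-0.0232 for glycolysis, -0.0171 for G1/S, -0.013 for matrix, -0.00993 for angiogenic factors, -0.0653 for histones). Estimates above the preset were 0.0683 for G2/M, 0.0882 for ATF4 and 0.0114 for NF-kB. Its higher p-values thus do not measure correlation between members alone. For single genes of the axis an exact permutation test was run on log2(FPKM + 1).

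Genes named in the text follow a rule set before the data were examined. It takes SPRY4-IT1, SPRY4, EZH2 and VEGFA, the 12 largest rises and the 12 largest falls among official symbols past the threshold with a mean FPKM of at least 1 in the higher group and no overlap between groups, and up to 2 risers and 2 fallers with the smallest p per main list. Other genes named in the text, such as SPRY4-AS1, CA9, GAPDH, MKI67, HGF and members of the cell type and RNA quality lists, were chosen after their values were seen. Some genes that the rule takes are not reported here.

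Alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, no filter, a filter at FPKM 5 in 3 libraries, limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.01, median centring, quantile normalization, no variance trend and array weights, a replicate block, leaving out each library, and for the lists an estimated correlation and fry. Counts divided by 4, library totals without TMM and the counts without the 20 most abundant genes were added after seeing the data. Replicates of a group differed by far more than counting noise (chi-square per gene of 69.97 to 101.3, or 17.49 to 25.32 at 4 counts per pair), so no library was taken for a copy of another.

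On simulated counts for the 18322 genes, the test recovered 5 of 67 genes changed by 1.5-fold (7.46%), 34 of 67 changed by 2-fold (50.7%) and 58 of 66 changed by 4-fold (87.9%), and 7.27% of its calls were false. In the same simulation 1 list was raised by 1.5-fold, which ranked 1 among the lists, and 2 lists passed camera. Far fewer genes were changed there than the 4827 called in the data. The adjusted threshold was thus stricter, and the recovered shares do not carry over to the data. Each gene was also drawn on its own, so list members had no correlation. The scan for 7-base words used 3' UTRs of GENCODE release 29 with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. It covered genes with at least 2 CPM, 3' UTRs of at least 50 bases and words present in at least 100 genes, with log2 differences limited to 2 either way and corrected for 3' UTR length and GC content, and ranked words by the mean over its standard error. On simulated values it ranked a lowered word 1.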

Results

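U87 is an established human glioma cell line. Poly(A) RNA was sequenced from 3 libraries of cells transfected with an siRNA against SPRY4-IT1, a long non-coding RNA transcribed from within the SPRY4 gene, and from 3 libraries of cells given a scramble siRNA. They are called knockdown and control here. The deposited table lists 60612 genes, with an estimated count and an FPKM value per library. Total counts were 61767069, 57784529 and 58872353 in the control libraries and 57077251, 58465790 and 57119035 in the knockdown libraries. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

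The first question was whether the targeted RNA and the genes named in the title of the series differed. SPRY4-IT1 itself was not tested, as no entry of the deposited table was matched to its name. Its RefSeq span on GRCh38 (chromosome 5, 142317620 to 142318322) lies inside SPRY4 and holds 2 small table entries. Together they had 0, 3 and 5 counts in the control libraries (8 in all). In the knockdown libraries they had 4, 0 and 0 counts (4 in all), too few to show a difference at this depth. The knockdown of the target was therefore not checked by these values, and the groups are as the labels give them.

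VEGFA, which encodes a growth factor of blood vessels, fell from 2468 ± 35.9 to 1233 ± 7.13 CPM (counts scaled by library total and TMM factor; mean ± SD, n = 3 per group), 2.00-fold lower (log2 difference -1.0, standard error 0.0401, adjusted p = 3.64e-05). EZH2, the catalytic subunit of the histone methyltransferase complex PRC2, fell from 80.3 ± 6.55 to 50.3 ± 4.0 CPM, 1.60-fold lower (log2 difference -0.67, standard error 0.0903, adjusted p = 0.00265). SPRY4, the host gene, stood at 20.3 ± 4.41 CPM in control and 28.9 ± 1.88 CPM in knockdown libraries and did not pass (log2 difference 0.51, standard error 0.165, adjusted p = 0.0647). VEGFA lies on chromosome 6 (43770184 to 43786487), EZH2 on chromosome 7 (148807383 to 148884321) and SPRY4 on chromosome 5 (142310427 to 142326455). For all 3 genes the libraries of the groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The SPRY4 call depends on the setting. It passed with DESeq2 (adjusted p = 0.0184) and without control replicate 3 (adjusted p = 0.0406), and over the alternatives its adjusted p ranged from 0.0184 to 0.172 and its log2 difference from 0.35 to 0.65. SPRY4-AS1 is a non-coding gene on the opposite strand (chromosome 5, 142325293 to 142533702). Its span overlaps that of SPRY4 at the 5' ends of both, but their exons do not overlap in GENCODE release 29. SPRY4-AS1 rose from 0.848 ± 0.0722 to 1.69 ± 0.440 CPM (log2 difference 0.99, standard error 0.282, adjusted p = 0.0419). It passed in 6 of 13 alternative fits and, with 1 library left out, only without knockdown replicate 1 (0.0276; from 0.0794 to 0.131 without any other), with adjusted p from 0.0235 to 0.131 over the alternatives.

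**Figure D1:**
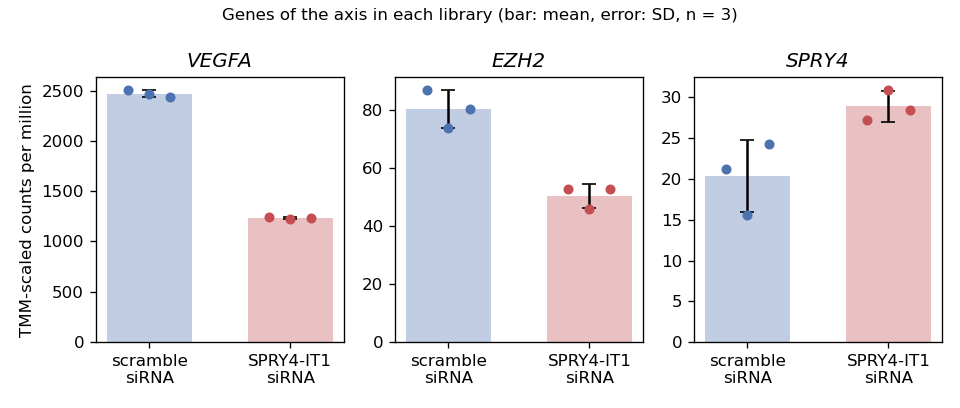
TMM-scaled CPM (vertical axes, starting at 0) of VEGFA, EZH2 and SPRY4 in each of the 6 libraries, with points for libraries, bars for group means and error bars for the SD (n = 3). VEGFA was 2.00-fold and EZH2 1.60-fold lower with the SPRY4-IT1 siRNA, and the difference in SPRY4 did not pass the test.

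Over the transcriptome, the question was which genes differed between knockdown and control cells. TNFSF15, a cytokine of the TNF family that inhibits vessel growth, had 9, 8 and 4 counts in the control libraries and 3553, 3749 and 3527 in the knockdown libraries (log2 difference 8.93, standard error 0.200, adjusted p = 1.3e-05). The control counts lie above the floor of 3 counts but under the 12 that it becomes at 4 counts per read pair, so the size of the rise is uncertain. Over the alternatives the log2 difference ranged from 2.87, on median centred log2(FPKM + 1), to 9.10, without control replicate 1. The added 1 far exceeds the control mean of 0.0118 FPKM and so compresses the lower value. With 1 library left out, the edgeR range was 8.65 to 9.10. TNFSF15 lies on chromosome 9 (114784652 to 114806039). SPP1, the secreted glycoprotein osteopontin, rose from 42.5 ± 3.82 to 534 ± 34.3 CPM, 12.6-fold higher, and SP140, a nuclear body protein, rose 13.4-fold. The chemokine CCL20 fell from 7.66 ± 1.07 to 0.490 ± 0.189 CPM, 15.6-fold lower, and the matricellular protein CCN5 fell 10.4-fold. Of 18322 genes tested, 4827 (26.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 2402 rose and 2425 fell. A change of at least 2-fold was found in 1141 of them (569 rose, 572 fell).

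Among the 12 largest rises were also LINC00520 (14.8-fold), the tight junction gene CLDN1 (8.92-fold), the muscle Z-disc gene MYOZ2 (8.85-fold), the cytokine IL36B (8.48-fold), the cornified envelope gene SPRR2D (7.46-fold), LINC02154 (7.31-fold), the proton pump subunit ATP6V0D2 (7.01-fold) and the actin-bundling gene LCP1 (6.42-fold). TEX48, a neighbour of TNFSF15 on chromosome 9, had 10 counts in 1 control library and none in the other two, against 106, 115 and 100 counts in the knockdown libraries. Its adjusted p was 0.0168 (edgeR), and over the alternatives it ranged from 5.42e-06 to 0.0503, the highest without knockdown replicate 2. Its log2 difference of 4.89 became 9.72 without control replicate 3 and 4.30 without control replicate 1. Among the 12 largest falls were PPL, which encodes periplakin (7.71-fold lower), FAIM2 (7.53-fold), PDXP (7.11-fold), TNFAIP2 (6.23-fold), IGFBP1 (6.06-fold), ATOH8 (5.50-fold), SMAD6, an inhibitor of BMP signalling (5.39-fold), and SERPINA6 (5.33-fold). BGLAP (11-fold lower) had 122, 92 and 82 counts in control and 1, 26 and 1 in knockdown libraries, and PDE6G (10.4-fold lower) had 94, 54 and 105 against 11, 14 and 0. Both calls are uncertain. BGLAP did not pass when any library other than knockdown replicate 2 was left out (adjusted p from 0.0983 to 0.116), and without that library its log2 difference was -6.49. PDE6G did not pass when any library other than knockdown replicate 3 was left out (adjusted p from 0.0557 to 0.0989). BGLAP and PDXP each overlap another gene on their strand, so counts may be shared.

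**Figure D2:**
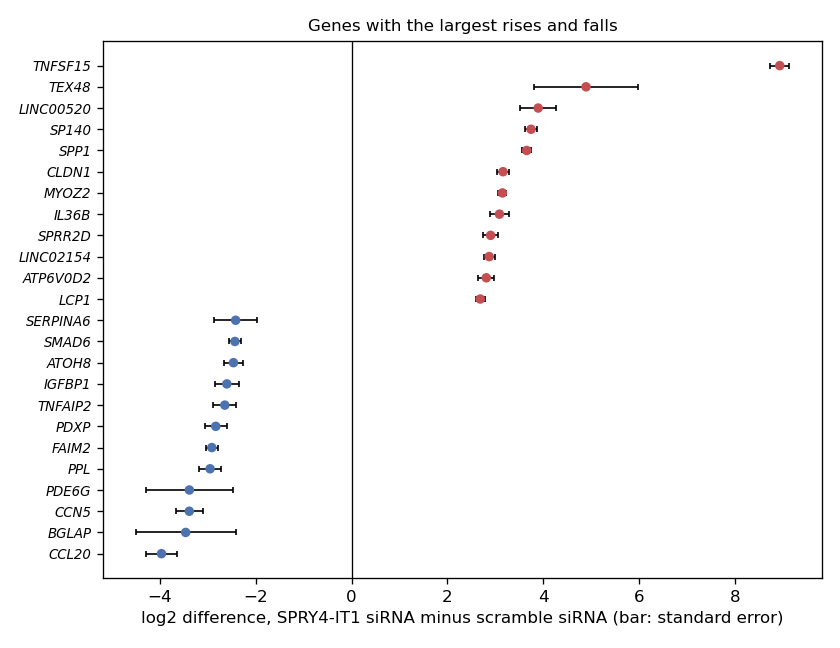
Log2 difference between SPRY4-IT1 siRNA and scramble siRNA (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls, with bars for the standard error. TNFSF15 stands apart at 8.93, a size that is uncertain because its control counts are few, and CCL20 has the largest fall at -3.96.

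The groups did not overlap for 8239 genes (45% of those tested, where chance gives 10%). With library totals alone in place of TMM scaling, 3331 genes rose and 1746 fell, a rise in 65.6% of calls against 49.8%, with the median of all genes moved by 0.11 on the log2 scale. On log2(FPKM + 1) without further scaling, limma called 3074 rises and 1677 falls (64.7% rises). Replication-dependent histones, mostly without a poly(A) tail and used here as a sign of RNA selection, rose with the knockdown in 6 of 12 members, and the 20 most abundant genes took 13.5% to 14.7% of counts in control and 11.8% to 12.5% in knockdown libraries.

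The 28 gene lists fixed before the data were examined were tested with camera, and 9 passed, of which hypoxia, glycolysis and G1/S also passed with an estimated correlation. Each of the other splits of the same 6 libraries gave 4 to 7 lists with the preset correlation, with 0 to 5 genes called. Those splits mix the groups unevenly, so part of the real difference stays in them. Whether that difference or the preset test itself gives their lists was not tested. The hypoxia response list fell most: of 36 members tested 0 rose, 32 fell and 4 did not pass, with a median log2 difference of -0.97. Carbonic anhydrase CA9 fell from 685 ± 50.3 to 176 ± 3.20 CPM (3.90-fold lower, n = 3). PFKFB3 and PFKFB4, which make the activator of phosphofructokinase, fell 3.43-fold and 3.39-fold. PFKFB4 overlaps UCN2 on its strand. Adjusted over the list alone, 1 rose and 32 fell. The camera adjusted p was 3.52e-32, and 0.00744 with an estimated correlation. The estimate was 0.00994, about the preset 0.01, so the higher value does not come from correlation between members. VEGFA is itself a member of this list.

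Glycolysis enzymes fell together: of 20 members 0 rose, 16 fell and 4 did not pass, with 1 rise and 17 falls adjusted over the list alone. ALDOC fell 2.87-fold, PGK1 2.14-fold (it overlaps ATP7A on its strand) and GAPDH from 20209 ± 1150 to 9188 ± 117 CPM (2.20-fold, n = 3). The lists share 13 genes. Of the 7 glycolysis genes outside the hypoxia list 4 fell, and of the 23 hypoxia genes outside glycolysis 20 fell. The adjusted p was 2.39e-14, and 0.0135 with an estimated correlation.

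Cell cycle genes also fell. Of 41 G1/S and DNA replication genes 0 rose, 22 fell and 19 did not pass (1 rose and 25 fell adjusted over the list alone); cyclin D1 (CCND1) was 1.73-fold and thymidine kinase TK1 2.19-fold lower. Its adjusted p was 3.87e-08, and 0.0216 with an estimated correlation. Of 41 G2/M and mitosis genes 0 rose, 29 fell and 12 did not pass (36 fell adjusted over the list alone), among them UBE2C (1.68-fold lower), KIF2C (1.66-fold lower) and the proliferation marker MKI67 (2.30-fold lower). This list passed at 3.7e-12 and did not with an estimated correlation (adjusted p = 0.0787).

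**Figure D3:**
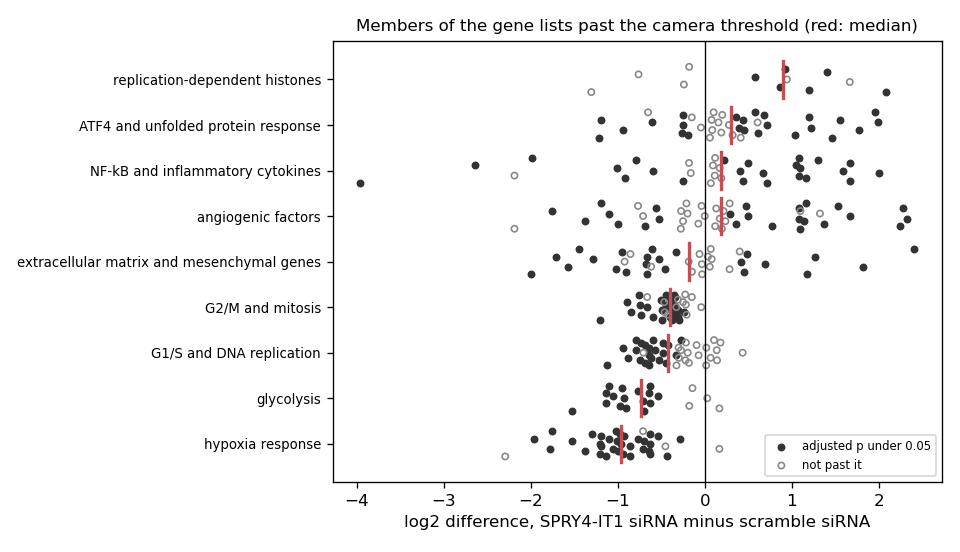
Log2 difference (horizontal axis) of each tested member of the 9 gene lists past the camera threshold, with filled points for genes at an adjusted p under 0.05, open points for the others and a red line for the list median. The hypoxia response list has the lowest median, -0.97, and 32 of its 36 members fell.

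The angiogenic factor list passed upward, although VEGFA fell. Of 44 members 16 rose, 8 fell and 20 did not pass (18 and 10 adjusted over the list alone). The urokinase gene PLAU rose 5.01-fold, the EGF receptor ligand HBEGF 4.74-fold and the hepatocyte growth factor gene HGF 4.84-fold, while the vascular peptide APLN fell 3.37-fold. VEGFA, ANGPTL4 and ADM are also hypoxia list members; of these 3 genes 2 fell, and of the other 41 genes 16 rose and 6 fell. The adjusted p was 0.0136, and 0.104 with an estimated correlation. Without control replicate 1 it was 0.0653, and over the alternatives it ranged from 1.24e-05 to 0.104. Of 21 angiogenesis inhibitors 4 rose, 4 fell and 13 did not pass (4 and 5 adjusted over the list alone; adjusted p = 0.947). TNFSF15, SEMA3A (3.27-fold), ADAMTS1 (1.62-fold) and COL4A2 (1.63-fold) rose, and TIMP1 (1.88-fold), SPARC (1.37-fold) and VASH1 (2.15-fold) were among those that fell.

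In the ATF4 and unfolded protein response list 16 of 38 members rose, 8 fell and 14 did not pass (18 and 8 adjusted over the list alone; adjusted p = 0.00109, and 0.287 with an estimated correlation). The amino acid stress genes TRIB3 (3.88-fold) and SESN2 (2.33-fold) rose, and the endoplasmic reticulum protein PDIA4 (2.32-fold) and STC2 (2.29-fold) fell. STC2 and DDIT4 are also in the hypoxia list. Of 33 NF-kB and inflammatory cytokine genes 16 rose, 8 fell and 9 did not pass (17 and 8 adjusted over the list alone; adjusted p = 0.0337, and 0.232 with an estimated correlation). IL1A (3.17-fold) and LIF (2.07-fold) rose, and ICAM1 (3.97-fold) and NFKBIA (1.89-fold) fell. That list did not pass without control replicate 1 (0.0653) or control replicate 2 (0.0525), and over the alternatives its adjusted p ranged from 0.000653 to 0.232. The NF-kB and angiogenic factor lists share IL6, CCL2, CXCL1, CXCL2, CXCL3, CXCL5 and CXCL8, so their results are not independent. Of 37 extracellular matrix and mesenchymal genes 8 rose, 15 fell and 14 did not pass, with the same 8 and 15 counts adjusted over the list alone (adjusted p = 0.0105, and 0.104 with an estimated correlation). TGFBI (3.99-fold) and COL1A1 (3.29-fold) fell, and COL5A2 (2.41-fold) and TNC (1.37-fold) rose. Of the 12 replication-dependent histones 6 rose, among them H2BC12 (2.64-fold), 0 fell and 6 did not pass (8 rose adjusted over the list alone; adjusted p = 0.00109, and 0.1 with an estimated correlation).

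The remaining lists did not pass camera, and the adjusted p of each is given with its counts. Of 11 PRC2 components 1 rose (EZH1, 1.32-fold), 3 fell (EZH2, RBBP4, 2.06-fold, and PHF1, 1.41-fold) and 7 did not pass, with 1 and 3 adjusted over the list alone (0.208). Of 19 genes reported as repressed by EZH2, 1 rose (FBXO32, 2.10-fold), 2 fell (VASH1, and IGFBP3, 3.36-fold) and 16 did not pass, with the same 1 and 2 counts adjusted over the list alone (0.618). IGFBP3 was at 1251, 1400 and 540 CPM in the control libraries and 306, 322 and 321 CPM in the knockdown libraries. Of 23 genes reported as miR-101 targets 8 rose, 4 fell and 11 did not pass, with 9 and 5 adjusted over the list alone (0.234). PTGS2 (2.47-fold) and SPHK1 (1.55-fold) rose, and LMNB1 (3.41-fold), EZH2, JAK2 (1.48-fold) and FBN2 (1.53-fold) fell. The SPRY4-IT1 axis list holds the 3 genes above (0 rose, 2 fell, 1 did not pass, with 1 and 2 adjusted over the list alone) and had an adjusted p of 0.1. It passed with DESeq2 (0.00102), with the FPKM 5 filter (0.0338, on 2 members) and with fry (0.00251), and over the alternatives the adjusted p ranged from 0.00102 to 0.374.

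Signalling and stress lists moved both ways. Of 31 MAPK feedback and immediate early genes 10 rose, 8 fell and 13 did not pass, with 13 and 8 adjusted over the list alone (adjusted p = 0.199); the feedback inhibitor SPRY2 rose 1.85-fold and FOSL1 fell 1.59-fold. Of 39 interferon response genes 6 rose (HERC6, 1.56-fold, and RSAD2, 2.34-fold, among them), 7 fell (MX2, 6.70-fold, and TRIM22, 1.57-fold, among them) and 26 did not pass, with 7 and 7 adjusted over the list alone (0.297). Of 29 p53 targets 7 rose (GDF15, 3.28-fold, among them), 6 fell (CCNG1, 3.78-fold, and POLH, 1.70-fold, among them) and 16 did not pass, with the same 7 and 6 counts adjusted over the list alone (0.947). Of 23 YAP and TEAD targets 2 rose (CCN1, 2.88-fold, and GADD45A, 1.39-fold), 8 fell (AXL, 1.75-fold, and F3, 1.63-fold, among them) and 13 did not pass, with 4 and 9 adjusted over the list alone (0.208).

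Of 27 cholesterol synthesis genes 7 rose (PMVK, 1.68-fold, among them), 5 fell (SCD, 2.31-fold, STARD4, 1.58-fold, SREBF1, 1.79-fold, FASN, 1.37-fold, and FDFT1, 1.19-fold) and 15 did not pass, with the same 7 and 5 counts adjusted over the list alone (adjusted p = 0.999). Of 25 PI3K and AKT pathway genes 2 rose (GSK3B, 1.29-fold, and PIK3CD, 1.24-fold), 3 fell (IRS1, 1.40-fold, and RPTOR, 1.3-fold, among them) and 20 did not pass, with the same 2 and 3 counts adjusted over the list alone (0.815). PIK3CD did not pass without knockdown replicate 1 (adjusted p = 0.0686) or 2 (0.0621) or with a replicate block (0.0534). Over the alternatives its adjusted p ranged from 0.00295 to 0.0686. Of 13 genes of the microRNA and siRNA machinery 0 rose, 3 fell (DICER1, 1.84-fold, AGO4, 1.63-fold, and DGCR8, 1.22-fold) and 10 did not pass, with 1 and 5 adjusted over the list alone (0.234). AGO4 did not pass without any 1 of the 3 control libraries or without knockdown replicate 3 (adjusted p from 0.0505 to 0.0709), and over the alternatives its adjusted p ranged from 0.00101 to 0.0709. For the p53, endothelial and cholesterol lists the test pointed upward while the median (-0.11, -0.06 and -0.01) and mean lay below 0.

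Markers of cell types also moved both ways. Of 12 astrocyte and glioma genes 2 rose (OLIG2, 2.60-fold, and NES, 1.25-fold), 4 fell (EGFR, 2.45-fold, CHI3L1, 2.27-fold, CD44, 1.60-fold, and VIM, 1.26-fold) and 6 did not pass, with 2 and 5 adjusted over the list alone (adjusted p = 0.105). Of 9 neuron markers 1 rose (MAP2, 2.48-fold), 3 fell (NEFM, 2.71-fold, SNAP25, 1.91-fold, and GAD1, 1.36-fold) and 5 did not pass, with 1 and 4 adjusted over the list alone (0.161). Of 9 endothelial markers 3 rose (ERG, 4.70-fold, ROBO4, 2.16-fold, and TEK, 1.54-fold), 2 fell (PECAM1, 2.97-fold, and ESAM, 2.62-fold) and 4 did not pass, with 3 and 3 adjusted over the list alone (0.947). Of 7 immune cell markers 0 rose, 1 fell (CD74, 1.95-fold) and 6 did not pass, with the same 0 and 1 counts adjusted over the list alone (0.336). Of 9 epithelial markers 1 rose (CLDN7, 1.84-fold), 1 fell (CLDN4, 3.42-fold) and 7 did not pass, with the same 1 and 1 counts adjusted over the list alone (0.411); without knockdown replicate 1 this list had an adjusted p of 0.0175, and over the alternatives it ranged from 0.0175 to 0.932.

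As signs of RNA quality, 2 of 13 mitochondrially encoded genes rose (MT-ND1, 1.33-fold, and MT-ND3, 1.26-fold), 2 fell (MT-CO2, 1.44-fold, and MT-ATP6, 1.26-fold) and 9 did not pass, with 2 and 3 adjusted over the list alone (adjusted p = 0.449). Of 45 ribosomal protein genes 2 rose (RPL14, 1.29-fold, and RPL24, 1.23-fold), 10 fell and 33 did not pass, with 2 and 13 adjusted over the list alone (0.105). That list passed downward without control replicate 1 (0.015) or 3 (0.0435), and over the alternatives its adjusted p ranged from 0.0149 to 0.932. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain.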

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

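The counts divided by 4, library totals alone and the counts without the 20 most abundant genes were chosen after seeing the data. VEGFA and EZH2 fell past the threshold in all 21 alternative fits, and 78 of 84 named genes kept their call in every fit that tested them, with the same sign in all. Calls numbered 3366 to 4156 (2-fold: 946 to 1073; rose 1644 to 2098, fell 1722 to 2078) when 1 library was left out. The FPKM 5 filter tests fewer genes and gave 2970 calls (1460 rose, 1510 fell), 304 of them at least 2-fold. On log2(FPKM + 1), 333 calls reached 2-fold, with pseudocounts of 0.1 and 0.01 615 and 655, and 335 median centred, 330 quantile normalized, 333 without a trend and 336 with array weights; these fits tested 11705 genes with another test, and the cause of the lower numbers was not tested apart from the pseudocount. Replicate numbers did not pair libraries (correlations of 0.00218, 0.0297 and 0.0109); a replicate block gave 3743 calls (890 at least 2-fold) and 6 lists, with adjusted p = 0.0641 for the angiogenic, NF-kB and matrix lists. SPRY4 passed in 10 fits, with log2 differences of 0.50 (DESeq2), 0.47, 0.61 and 0.63 (pseudocounts 1, 0.1 and 0.01), 0.39 (centred), 0.40 (quantile), 0.47 (no trend), 0.45 (array weights), 0.61 (library totals) and 0.65 (without control replicate 3); with 1 library left out it ranged from 0.35 to 0.65 and passed in no other such fit. The cause was not tested. Lists past the threshold numbered 9, 3 with an estimated correlation (0.0787 for G2/M, 0.287 for ATF4, 0.1 for histones, 0.104 for angiogenic and matrix, 0.232 for NF-kB) and 20 with fry, which does not compare a list with other genes. Hypoxia, glycolysis and G1/S passed in every test. On FPKM, adjusted p values past 0.05 with pseudocounts 1, 0.1 and 0.01, centring, quantile, no trend and array weights were 0.178, 0.171, 0.163, 0.0744, 0.0936, 0.209 and 0.178 for NF-kB and 0.0672, 0.0637, 0.0623, 0.106, 0.227, 0.0781 and 0.0729 for the matrix list, and 0.0672, 0.0662, 0.066, 0.0823 and 0.0771 for angiogenic factors with the 3 pseudocounts, no trend and array weights. With 1 library left out, adjusted p ranged from 0.01 to 0.0653 for angiogenic factors, 0.0176 to 0.0653 for NF-kB, 0.855 to 0.986 for angiogenesis inhibitors, 0.659 to 0.979 for p53, 0.889 to 0.964 for cholesterol and 0.846 to 0.998 for endothelial markers. In these fits angiogenesis inhibitors turned downward without each library but knockdown replicate 3 (0.886, 0.944, 0.855, 0.947 and 0.956), p53 without control replicate 2 (0.944) and knockdown replicate 1 (0.979), cholesterol without control replicates 1 (0.943) and 3 (0.889) and knockdown replicate 3 (0.925), and endothelial markers without knockdown replicate 1 (0.943). Lists that did not pass also turned direction in other fits, with these adjusted p values, the cause not tested: cholesterol 0.835 (DESeq2), 0.977 (RLE), 0.862 (no filter), 0.949 (FPKM 5) and 0.0581 (fry); endothelial 0.877 (DESeq2), 0.796 (fry), 0.936 (totals) and on FPKM 0.677, 0.661, 0.65, 0.657, 0.736, 0.724 and 0.713; angiogenesis inhibitors 0.838 (no filter), 0.835 (FPKM 5), 0.912 (block), 0.936 (totals) and on FPKM 0.654, 0.633, 0.563, 0.84, 0.856, 0.734 and 0.628; epithelial on FPKM 0.825, 0.853, 0.851, 0.904, 0.932, 0.794 and 0.808; p53 0.991, 0.994, 0.986, 0.967 and 0.942; interferon 0.991, 0.967 and 0.953; PI3K 0.936 (totals); and with quantile normalization 0.986 for EZH2-repressed, 0.411 for mitochondrial and 0.932 for ribosomal genes. BGLAP, PDE6G and TEX48 have few counts and kept their calls with the counts divided by 4. BGLAP did not pass in edgeR with no filter (adjusted p = 0.0817), a replicate block (0.0613) or library totals alone (0.0544). PDE6G did not pass with no filter (0.0568) or the block (0.094).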

Other observations

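The GO terms of the deposited table gave groups outside the fixed lists; they and the genes named from them were chosen after the data were seen. Of 2327 terms with 15 to 300 tested members, 32 passed camera and 0 passed with an estimated correlation (adjusted p = 0.9 for those named here). Of 29 genes of ribosomal large subunit biogenesis 20 rose and 0 fell (adjusted p = 7.8e-07), with the nucleolar factors EBNA1BP2 (1.77-fold) and RRS1 (1.79-fold). Of 61 proteasome genes 24 rose and 4 fell (0.0067); PSMD14 rose 1.76-fold and PSMC2 fell 1.58-fold. Of 43 genes of tRNA aminoacylation 21 rose and 6 fell (0.0319), with CARS1 up 1.57-fold. Of 25 genes of MHC class I antigen presentation 1 rose and 13 fell (0.0022). HLA-C fell 3.71-fold and HLA-B 2.68-fold, and these paralogs also overlap on their strand in the annotation, so their counts are uncertain. B2M had 35225, 34564 and 3344 counts in the knockdown libraries and did not pass (adjusted p = 0.457). The transcripts of the hypoxia factors HIF1A (860 ± 28.5 to 452 ± 11.9 CPM, 1.9-fold lower) and EPAS1 (334 ± 6.79 to 128 ± 1.56 CPM, 2.62-fold lower) also fell (n = 3).

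Of the tests below, those on transcript length, on coding sequence, on handling and on the other splits of the libraries were set before their results were seen, and the tests on scaling, on the word in list members, on 3' UTR length, on parts of the genes, on cell cycle genes and on miR-101 sites after. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 4827 calls, and the highest of the others gave 5. For 2-fold changes 1 split gave as many as the real 1141, with 5 the highest other, and for lists 1 gave as many as the real 9, with 7 the highest other. The 10 splits are too few for a share under 0.05. All but the real one mix the groups unevenly and so keep part of the real difference, and their counts do not measure chance alone.

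Genes of the hypoxia list fell together. Scaling or a few abundant genes would have to bring the median near 0, and its highest value over 4 scalings and without the 20 most abundant genes was -0.861. After a fit on transcript length and GC content the median was -0.994. In the 3' UTR, 5.71% of the 35 members searched held the word described next, against 8.22% of all genes searched. This argues against pairing of that word in the 3' UTR of most members. How many members hold it in the coding sequence is not reported here, so pairing there stays open. The design cannot separate handling of the dishes from the siRNA: the gap between the lowest control and the highest knockdown mean was 0.903 log2 CPM, and differences in cell density or medium, which may change oxygen, cannot be told apart from it. An effect of the siRNA, through SPRY4-IT1, HIF1A or EPAS1, stays open and was not tested, and as the 3' UTR of EPAS1 holds 1 GGAATCC and that of HIF1A 0, pairing of that word on EPAS1 stays open too.

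Genes whose 3' UTR holds the 7-base word GGAATCC lay lower than others. Among 15861 words in 11357 genes, ranked by the mean over its standard error, it was the lowest (934 genes, mean residual log2 difference -0.142, standard error 0.0163), with -0.133 for 1 site and -0.246 for 2 or more, and it was present in 13.7% of genes that fell and 5.67% of genes that rose. Picked as the lowest word in one part of the genes with no correction, it was then looked at in the other part. After the fit on 3' UTR length and GC content it lay -5.73 standard errors from the mean there. That fit took the words more than 4 standard errors from 0 from 442 to 8, so the value that remained argues against length and GC content as the cause. Picked after the fit, the word lay -5.56 standard errors from 0 in the other part. As it was already the lowest word over all genes and both parts share the 6 libraries, this is no independent check on a chance pick. With values also corrected for coding length and GC content, genes with the word only in the coding sequence lay low too (-0.0789, standard error 0.0149) but less so than those with it in the 3' UTR (-0.140; difference -0.0608, standard error 0.0244), as pairing of a small RNA seed in the 3' UTR would give, so an effect of the siRNA on unintended transcripts is a candidate explanation. The siRNA sequence is not used here. The reverse complement GGATTCC was next in this ranking (-5.54 standard errors, mean -0.0872), which pairing of 1 seed would not by itself give. The 3' UTRs of EZH2 and VEGFA hold 0 GGAATCC, and that of VEGFA holds 2 GGATTCC. Whether the coding sequences of EZH2 and VEGFA hold either word is not reported here, so direct pairing on either gene stays open.

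EZH2 fell, and miR-101 is named in the title of the series as a regulator of it. EZH2's -0.674 lay between the 5th (-0.879) and 95th (0.104) percentile of 82 cell cycle genes (median -0.403), 16 of which fell further. A general fall of cell cycle transcripts could give this value. An effect on EZH2 alone could lie in so wide a range too, so the comparison cannot tell them apart. The 1419 genes with the miR-101 site GTACTGT had a mean residual of -0.00412 (95% interval -0.0294 to 0.0211), which argues against a general effect on transcripts with the site. EZH2 holds 2 such sites. An effect on EZH2 alone or on translation stays open.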
